A study of Mus musculus with 15 samples.

How the data were processed

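RNA sequencing libraries of 5 mouse HDAC5-driven escaper cell lines were analysed from deposited tables, 1 per library, for a scramble hairpin and 2 hairpins against Hdac5 (15 libraries, 3 groups of 5). The group and replicate number of each library came from its label, and the series text names the 5 cell lines as the biological replicates. Whether the cultures of a line were handled on separate days is not stated, so p-values measure the spread between these libraries.

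Each deposited table gave a raw read count per gene, with Ensembl identifier, position, symbol, exon length and an RPKM value, per the file headers. Per the submitters' processing notes, CASAVA, STAR, TopHat, Cufflinks and HTSeq were used with the mm9 build; versions are not given in the sources used here. The gene positions did not match that build's name. Of 39179 genes, 37607 identifiers were found in GENCODE M21 (GRCm38), 99.98% of these on the same chromosome and 98.6% with a start within 10 kb, so coordinates are given as GRCm38. The deposited RPKM equalled the count scaled by exon length and by the total of all table entries, including 5 HTSeq summary entries. Those summary entries name no gene and were left out. Across libraries they held 26.9 to 30.9% of all entries as not uniquely aligned, 6.00 to 9.97% as matching no feature and 1.95 to 2.32% as ambiguous. Whether counting used strand is not stated, so counts of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies, whose shared reads fall under the not unique entries. Gene counts summed to between 94.6 and 159 M (mega-counts) per library. No pair of libraries agreed within sampling noise (lowest chi-square per gene 109.6 over 105 pairs).

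The design had been written for normalized values and limma, with edgeR as the test should the tables hold counts. Since they did, edgeR was used. Groups, designs, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes with an RPKM of at least 1 in at least 5 of the 15 libraries were tested (10601 genes, of which 9800 were protein-coding in GENCODE M21). Counts were scaled by TMM (factors 0.972 to 1.02) and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 with 1 coefficient per group and no covariate. The 4 comparisons were the mean of both hairpins against scramble, each hairpin against scramble, and shHDAC5-1 minus shHDAC5-2. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Exact permutation tests of 5 against 5 libraries were made for Hdac5.

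Replicate numbers name the same cell line in each group and therefore pair the libraries. Correlations of same-line libraries' deviations from their group means lay between 0.359 and 0.864 (median 0.648, 15 pairs), against -0.627 to 0.305 for 60 pairs of different lines and groups. The biological coefficient of variation was 24.5% without and 12.2% with the line as a block. The SEs and p-values of the main fit, which has no block, therefore include differences between lines. The fit with this block is the main alternative.

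The text names Hdac5, a fixed set of single genes (Socs3, Ccl2, Ccl7, Cxcl1, Il6, Stat3, Tgfb1, Kras, Trp53, Yap1 and Myc), and genes chosen by rule. For both hairpins these were the 10 largest rises and 10 largest falls among called genes with a mean RPKM of at least 1 and the same direction in all 10 pairs of a hairpin library and its own line's scramble library. For each hairpin and between the hairpins the 5 largest in each direction were taken by the same rule over 5 of 5 lines. Of each list up to 4 members with the smallest adjusted p were named. Predicted genes, pseudogenes, mitochondrial and small RNA genes were not named, and Hdac5 was left out of the rankings.

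The 24 lists held 609 entries: histone deacetylase family, SOCS and cytokine receptor signalling, chemokines and inflammatory cytokines, NF-kB targets, interferon response, MEF2 and class IIa deacetylase partners and targets, MAPK output, YAP and TEAD targets, TGF-beta response, epithelial and mesenchymal markers, G1/S and G2/M cell cycle, p53 targets, unfolded protein and amino acid stress response, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, lysosome and autophagy, receptor tyrosine kinases and ligands, and markers of macrophages and leukocytes, fibroblasts, endothelium, and acinar and endocrine cells. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. In total 24 genes were in more than 1 list.

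Alternatives were the line block, DESeq2 1.42.0, DESeq2 size factors, quantile normalization, robust empirical Bayes, limma on log2(RPKM + 0.1), fry, no filter, a filter at RPKM 5, fits of only the groups compared, and each line left out. Chosen after seeing the data were limma on log2(RPKM + 1), library totals as the scaling, and offsets for GC content and length, for which 99.2% of tested genes had a value. Shared scramble libraries were treated by 20 simulations of unchanged groups and by 20 splits of the scramble libraries between the hairpins. The test was run on simulated data with 200 of 10601 genes changed. For both hairpins it recovered 50.7, 91.0 and 100% of genes changed 1.5-, 2- and 4-fold, with 4 false calls among 165, and for the difference between the hairpins, where no change was simulated, it made 0 calls, as did limma and DESeq2. With shHDAC5-1 and shHDAC5-2 alone it recovered 32.8 and 40.3% of genes changed 1.5-fold. DESeq2 made 22 false calls among 193 for both hairpins, and 22 and 21 among 182 for the single hairpins.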

Results

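Total RNA from 5 mouse pancreatic ductal adenocarcinoma cell lines was sequenced. The lines came from the iKPC model, in which an oncogenic Kras transgene, written KRAS*, can be switched on and off. They were escaper lines, meaning cells able to grow independently of KRAS*, and the labels describe them as driven by HDAC5, a class IIa histone deacetylase that represses transcription together with corepressors. Each line carried a scramble short hairpin RNA as the control or either of 2 hairpins against Hdac5, named shHDAC5-1 and shHDAC5-2. This gave 15 libraries in 3 groups of 5, with 1 library per line in each group, and the replicate number named the line. Counts assigned to genes, in mega-counts (M), in replicates 1 to 5 were 99.1, 117, 94.6, 126 and 114 M in the scramble libraries. They were 111, 123, 120.3, 121 and 138 M with shHDAC5-1, and 113, 125, 159, 116.5 and 101 M with shHDAC5-2. The group means were 110.1 ± 12.9, 123 ± 9.53 and 123 ± 21.7 M (SD, n = 5). Mitochondrial genes took between 0.809 and 1.11% of the gene counts in the scramble libraries, between 0.541 and 0.838% with shHDAC5-1 and between 0.642 and 0.891% with shHDAC5-2. All levels below are counts-per-million (CPM) after TMM scaling, as mean ± SD over the 5 lines. Log2 fold changes are given with their standard error (SE), and gene-wise adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 10601 genes.

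Hdac5, the targeted gene, was lower in every hairpin library than in every scramble library. The gene (ENSMUSG00000008855) lies on chromosome 11 from 102194432 to 102230166 in the coordinates of the files, which match the Ensembl GRCm38 gene models. Its level in replicates 1 to 5 was 645, 982, 698, 733 and 770.3 CPM with scramble. It was 104, 73.9, 72.1, 78.5 and 53.3 CPM with shHDAC5-1, and 65.1, 87.9, 62.2, 82.9 and 52.9 CPM with shHDAC5-2. The fitted level with shHDAC5-1 and shHDAC5-2 was 9.96 and 9.18% of that with scramble. With 0.5 CPM added to each level, single libraries held 6.98 to 16.2% and 6.92 to 11.4% of the level of their own line's scramble library. Each hairpin differed from scramble in an exact permutation test of 5 against 5 libraries (two-sided p = 0.00794 over 252 splits, the smallest this test allows). The test ignores the pairing of libraries by line. Averaged over both hairpins, the log2 fold change was -3.39 ± 0.15 (adjusted p = 5.2e-09). Between shHDAC5-1 and shHDAC5-2 the difference was 0.12 ± 0.17 on the log2 scale and did not pass (adjusted p = 0.691).

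**Figure D1:**
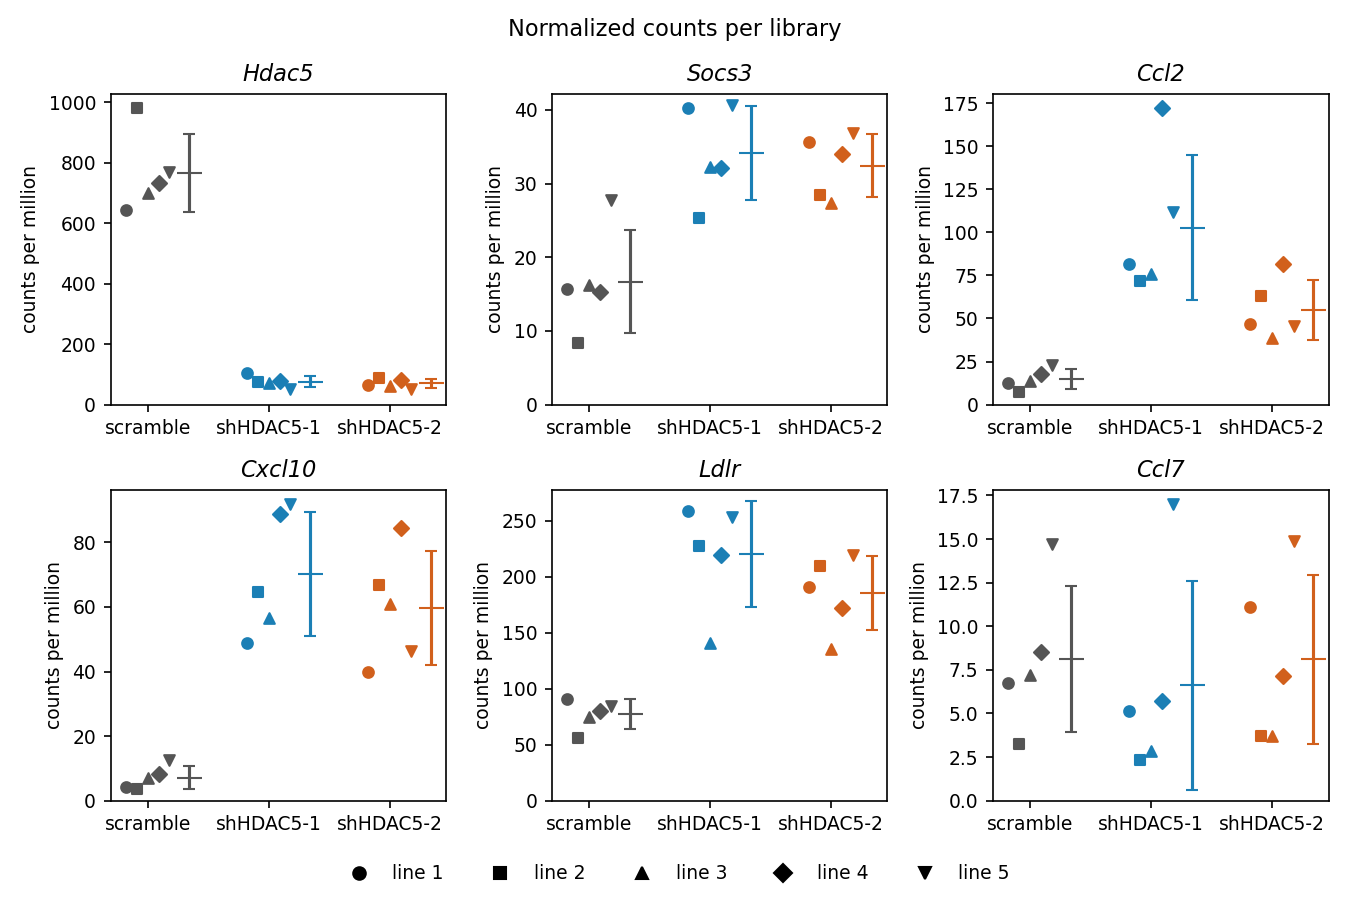
Levels of 6 genes in the 15 libraries, on a linear axis in counts-per-million (CPM). Marker shapes stand for the 5 cell lines and bars for the mean ± SD of each group. Hdac5 lies between 52.9 and 104 CPM in the hairpin libraries and between 645 and 982 CPM in the scramble libraries. Ldlr was added to the panels after its values were seen.

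In a principal component analysis of log2 CPM values, the first component held 30.1% of the variance and parted the groups. Scramble libraries lay between -43.7 and -28.5, shHDAC5-1 libraries between 4.28 and 18.5, and shHDAC5-2 libraries between 19.5 and 31.2. The second component held 26.01%, and on it the libraries of replicate 2 lay highest, between 26.2 and 42.0, and those of replicate 5 lowest, between -44.1 and -29.7, while those of the other lines overlapped between -10.7 and 19.7.

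**Figure D2:**
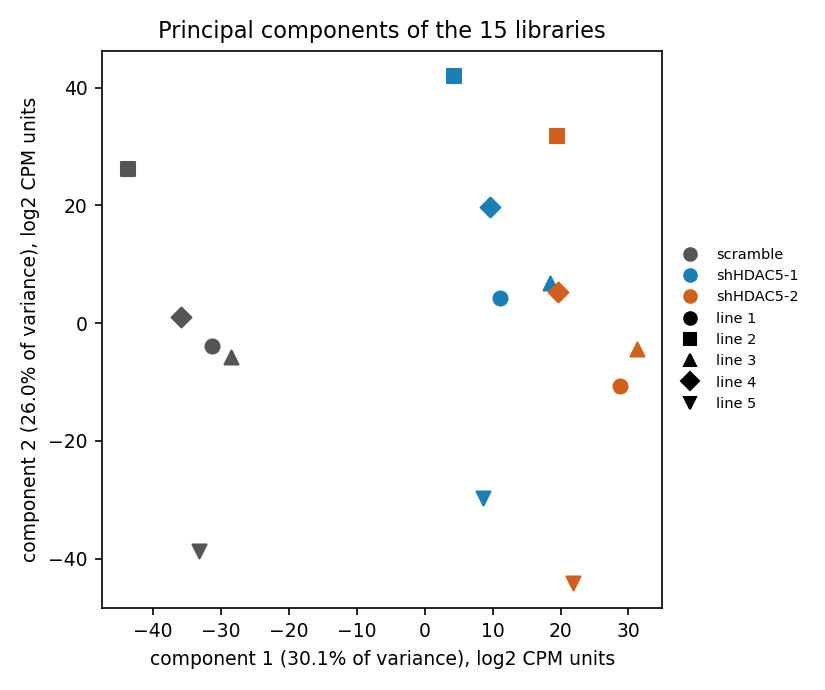
The 15 libraries on the first and second principal components of their log2 CPM values, coloured by group and marked by cell line. The axes give the share of variance, 30.1% and 26.01%. All 5 scramble libraries lie at the negative end of the first component.

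The comparison of both hairpins with scramble asks what knockdown of Hdac5 changed in these cells. The genes with the largest rises in all lines included chemokines and interferon-induced genes. Ccl9, a chemokine that attracts myeloid cells, rose from 1.45 ± 0.622 CPM with scramble to 17.9 ± 7.51 and 25.3 ± 9.31 CPM with shHDAC5-1 and shHDAC5-2 (log2 fold change 3.88 ± 0.36, adjusted p = 2.5e-06). Cxcl10, an interferon-induced chemokine for T cells, rose by 3.19 ± 0.32 on the log2 scale (adjusted p = 4.7e-06). The antiviral enzyme Rsad2 rose by 3.57 ± 0.95 (adjusted p = 0.00827) and the guanylate-binding protein gene Gbp4 by 3.10 ± 0.60 (adjusted p = 0.00102). Apart from Hdac5, the largest falls were those of Car6, a secreted carbonic anhydrase, and of the cytochrome c oxidase subunit gene Cox6a2, with log2 fold changes of -3.83 and -3.04 (adjusted p = 1.1e-05 and 3.6e-05).

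The other leading rises were those of Tdpoz4, Klhl30, Plvap, Plekhg4, Upk3bl and Abcg1. Klhl30, a kelch-family gene on chromosome 1 from 91351016 to 91362416, rose from 2.65 ± 2.05 CPM to 46.4 ± 20.8 and 38.6 ± 20.2 CPM (log2 fold change 4.0 ± 0.49, adjusted p = 2.6e-05). Abcg1, a cholesterol exporter of the ABC transporter family, rose by 2.97 ± 0.21 (adjusted p = 3.0e-07). Plvap, known for the diaphragms of endothelial fenestrae, rose by 3.31 ± 0.27 (adjusted p = 1.0e-06), and the Rho exchange factor gene Plekhg4 by 3.14 ± 0.43 (adjusted p = 6.3e-05). Tdpoz4 had a log2 fold change of 4.12 ± 0.83 and Upk3bl of 3.03 ± 0.44 (adjusted p = 0.00135 and 0.000103). Among the falls, Car6 on chromosome 4 (150187015 to 150201332) went from 120.3 ± 39.0 CPM to 10.4 ± 6.05 and 6.82 ± 4.53 CPM (log2 fold change -3.83 ± 0.42). Avil, which encodes the actin-binding protein advillin, went from 483 ± 70.4 CPM to 74.1 ± 29.9 and 99.2 ± 42.7 CPM (log2 fold change -2.49 ± 0.24, adjusted p = 3.8e-06). The epidermal growth factor receptor (EGFR) ligand gene Areg had a log2 fold change of -2.59, the angiopoietin-like gene Angptl6 of -2.79, with the smallest fall in replicate 3 at -1.58, and the glycogen-binding gene Stbd1 of -2.74. Id1, an inhibitor of DNA binding that responds to BMP signals, had one of -2.05, the cytokine receptor-like gene Crlf1 of -2.48, Prl2c3 of -2.26 and the esterase gene Esd of -1.87, with adjusted p-values of these 7 genes between 8.1e-08 and 0.000577. Tdpoz4, Prl2c3 and the guanylate-binding genes have near-identical copies, so their counts are uncertain.

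In all, 4098 of 10601 genes passed an adjusted p of 0.05, of which 2025 were higher and 2073 lower with the hairpins, and 429 were at least 2-fold higher against 83 at least 2-fold lower. These calls are of the mean of both hairpins, and a gene can pass with a change in 1 of them. With the cell line as a block 6592 genes passed. A stricter expression filter, which tested 6603 genes, gave 2702. The split was 2532 higher and 2038 lower with no filter, and 1833 and 2600 with a correction for GC content and length.

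Chemokine and inflammatory cytokine genes rose together. Of 16 measured members, 12 rose, 0 fell and 4 did not pass, and 13 rose when adjusted over the list alone. Ccl2, the monocyte chemoattractant on chromosome 11 from 82035571 to 82037453, rose from 14.9 ± 5.90 CPM to 103 ± 42.0 and 55.1 ± 17.4 CPM (log2 fold change 2.33 ± 0.30, adjusted p = 3.7e-05). Cxcl1, a neutrophil chemoattractant, rose by 2.18 ± 0.33 (adjusted p = 0.000138) and the inflammasome cytokine gene Il18 by 1.51 ± 0.17 (adjusted p = 1.4e-05). Ccl7, the neighbour of Ccl2, did not pass, with 8.10 ± 4.19 CPM with scramble and 6.61 ± 6.00 and 8.10 ± 4.85 CPM with the hairpins (log2 fold change -0.15 ± 0.48, adjusted p = 0.838). Il6 was too low to test, at 0.0549 ± 0.0597 CPM with scramble and 0.0384 ± 0.0321 and 0.0245 ± 0.0110 CPM with the hairpins. The list as a whole was higher (camera adjusted p = 1.0e-08), also with an estimated correlation between genes (adjusted p = 0.0352), but not with that and the line as a block together (adjusted p = 0.136).

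Targets of the transcription factor NF-kB rose as well. Of 17 measured members, 12 rose, 0 fell and 5 did not pass, and 13 rose when adjusted over the list alone, while 13 were higher and 1 lower with the line as a block. Irf1, an interferon regulatory factor, rose from 43.2 ± 6.91 CPM to 129.7 ± 23.5 and 159 ± 22.9 CPM (log2 fold change 1.73 ± 0.14, adjusted p = 7.7e-07). The NF-kB inhibitor genes Nfkbia and Nfkbie rose by 1.39 ± 0.12 and 1.14 ± 0.19, and the feedback deubiquitinase gene Tnfaip3 by 1.05 ± 0.15 (adjusted p = 1.8e-06, 0.000373 and 8.8e-05). The list had a camera adjusted p of 8.5e-07, and an adjusted p = 0.0969 with an estimated correlation.

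Interferon response genes were higher too. Of 28 measured members, 20 rose, 0 fell and 8 did not pass, and 21 rose when adjusted over the list alone. With shHDAC5-1 alone 14 were higher and 1 lower, and with shHDAC5-2 alone 22 and 0. Gbp2 went from 13.3 ± 1.41 CPM to 80.3 ± 21.2 and 120.3 ± 40.3 CPM (log2 fold change 2.89 ± 0.22, adjusted p = 6.6e-07). The ADP-ribosyltransferase gene Parp14 rose by 2.34 ± 0.19 and Ddx58, which encodes the RNA sensor RIG-I, by 1.5 ± 0.15 (adjusted p = 7.9e-07 and 4.5e-06). The camera adjusted p was 4.4e-13, and the adjusted p = 0.0592 with an estimated correlation. Cxcl10 belongs to this list and to the chemokines.

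Genes of cholesterol synthesis and uptake rose together. Of 24 measured members, 19 rose, 0 fell and 5 did not pass, with 19 higher also when adjusted over the list alone. With shHDAC5-1 alone 18 were higher and 2 lower, and with shHDAC5-2 alone 21 and 0. Fdps, which makes farnesyl diphosphate, rose from 41 ± 3.61 CPM to 155 ± 29.1 and 126 ± 23.1 CPM (log2 fold change 1.77 ± 0.13, adjusted p = 4.7e-07). Insig1, the sterol-regulated retention protein, rose by 1.89 ± 0.18, the sterol oxidase gene Sc4mol by 0.98 ± 0.11, and Srebf2, which encodes the master transcription factor of the pathway, by 0.94 ± 0.11 (adjusted p = 2.5e-06, 1.4e-05 and 1.3e-05). The camera adjusted p was 2.7e-13, and the adjusted p = 0.0592 with an estimated correlation.

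In the list of glycolysis and hypoxia genes, 15 of 27 measured members rose, 4 fell and 8 did not pass, with 17 higher and 4 lower when adjusted over the list alone. The aldolase gene Aldoc rose by 1.95 ± 0.21 from 1.85 ± 0.416 CPM, the hexokinase gene Hk1 by 0.60 ± 0.10, the collagen prolyl hydroxylase gene P4ha1 by 0.50 ± 0.09 and the glycolytic mutase gene Pgam1 by 0.44 ± 0.09 (adjusted p between 8.2e-06 and 0.00161). The camera adjusted p was 0.00593, and the adjusted p = 0.362 with an estimated correlation. Among YAP and TEAD targets, 10 of 23 members rose, 3 fell and 10 did not pass, with 11 higher and 3 lower when adjusted over the list alone and 11 and 5 with the line as a block. The matricellular gene Cyr61 rose from 506 ± 94.9 CPM to 1872 ± 323 and 1267 ± 216 CPM, a log2 fold change of 1.61 ± 0.14, and the growth factor gene Tgfb2 rose by 2.24 ± 0.22 (adjusted p = 1.8e-06 and 4.1e-06). Arhgef17 and Myof rose by 0.67 ± 0.13 and 0.62 ± 0.13 (adjusted p = 0.000988 and 0.0016). The list's camera adjusted p was 0.0443, the blocked value was 0.0548, and the adjusted p = 0.497 with an estimated correlation. Without replicate 3 or 5 the adjusted p was 0.118 and 0.0822.

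Epithelial markers were scarce, with 7 of the list measured. Of these, 4 rose, also when adjusted over the list alone, namely the transcription factor gene Elf3, the tight junction gene Cgn and the keratins Krt7 and Krt18, by 1.65 ± 0.25, 1.52 ± 0.41, 2.23 ± 0.75 and 0.53 ± 0.19 (adjusted p between 0.000155 and 0.0392). The camera adjusted p was 0.0478, the adjusted p = 0.474 with an estimated correlation, and it was 0.0522 without replicate 2. With shHDAC5-1 alone 4 rose (camera adjusted p = 0.0115). With shHDAC5-2 alone 2 rose and 5 did not pass (camera adjusted p = 0.187). Among 27 mesenchymal markers, 8 rose and 1 fell, with the same counts when adjusted over the list alone, and with the line as a block 15 were higher and 8 lower. The type I collagen gene Col1a1 rose from 603 ± 155 CPM to 2112 ± 899 and 3785 ± 1050 CPM (log2 fold change 2.23 ± 0.28, adjusted p = 3.0e-05), and the matrix gene Sparc by 1.38 ± 0.16 (adjusted p = 1.5e-05). Col1a2 rose by 1.36 ± 0.27 and the transcription factor gene Zeb1 by 0.69 ± 0.14 (adjusted p = 0.00107 and 0.0011). Fn1, the fibronectin gene, named after its values were seen as the member that fell, had a log2 fold change of -0.52 ± 0.19 (adjusted p = 0.0406). For the mean of both hairpins the list did not pass (camera adjusted p = 0.0734, and adjusted p = 0.689 with an estimated correlation). Its blocked value passed (adjusted p = 0.00395), though not with an estimated correlation (adjusted p = 0.332), as did the values without replicate 4 or 5 in camera (adjusted p = 0.0198 and 0.0479). With shHDAC5-2 alone 10 members rose and 0 fell, and the list passed (camera adjusted p = 0.00956), though not with an estimated correlation (adjusted p = 0.649). With shHDAC5-1 alone 5 rose and 1 fell, and it did not pass (camera adjusted p = 0.469).

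**Figure D3:**
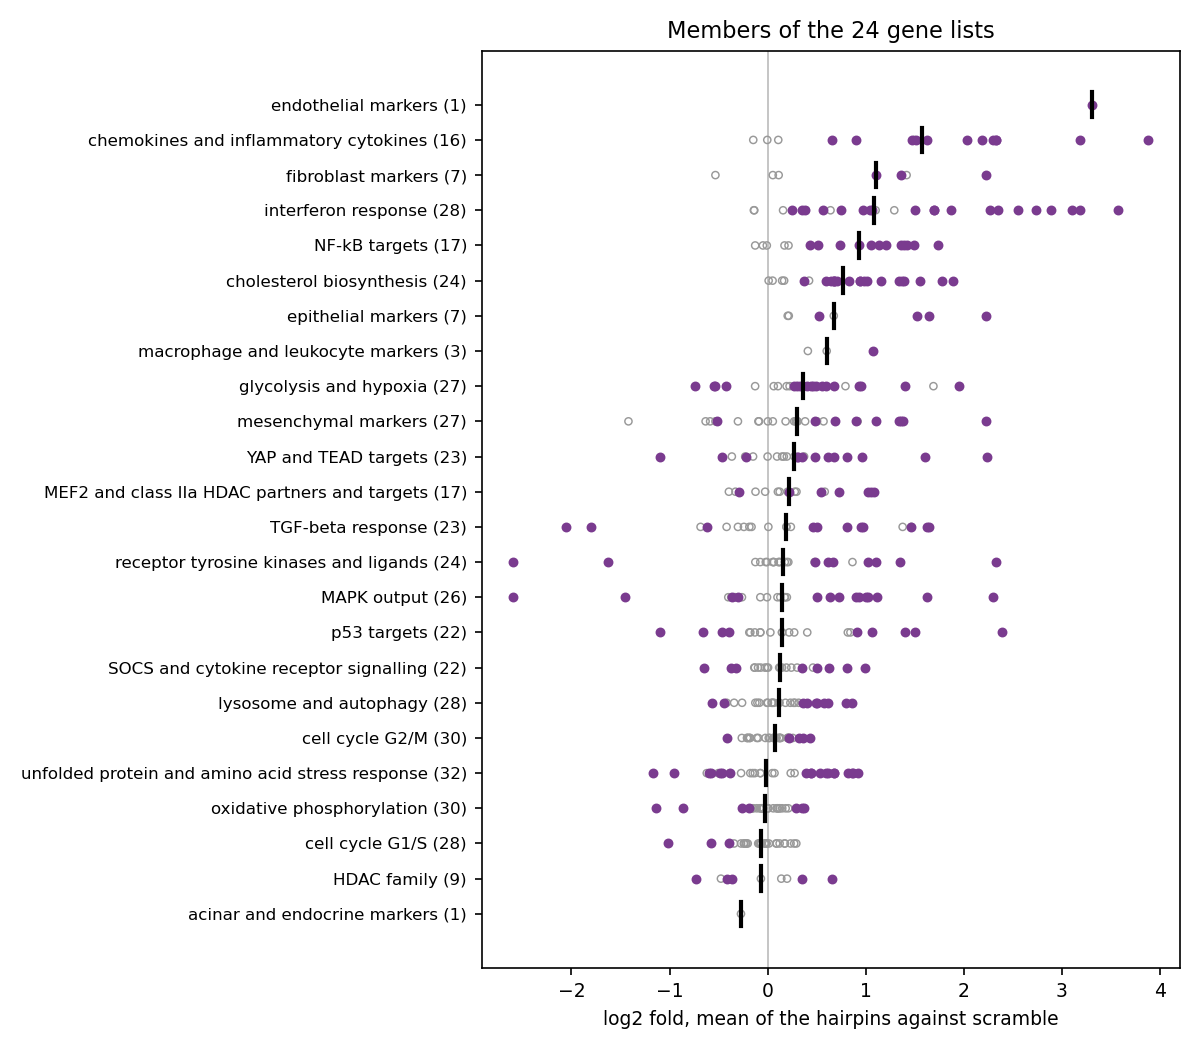
Log2 fold changes of the members of the 24 gene lists for both hairpins against scramble. Each dot is a measured gene, filled where its adjusted p is under 0.05, the black bar is the list's median and the number in brackets counts the measured members. In the chemokine, NF-kB, interferon and cholesterol lists every filled dot lies above 0.

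The markers of other cell types were mostly unmeasured. Of the macrophage and leukocyte markers 3 were measured and 1 rose, Cd14, the lipopolysaccharide co-receptor, from 2.86 ± 1.79 CPM to 7.45 ± 2.50 and 4.90 ± 1.55 CPM (log2 fold change 1.08 ± 0.34, adjusted p = 0.0194; list camera adjusted p = 0.358). Adjusted over the list alone the count was also 1, and with the line as a block it was 2. With shHDAC5-1 alone 2 rose, and with shHDAC5-2 alone 0 passed, Cd14 included. With the line as a block 1 member was higher with shHDAC5-2 alone. Of 7 fibroblast markers, 3 rose, also when adjusted over the list alone, and all were collagens, Col1a1, Col1a2 and Col3a1 (list camera adjusted p = 0.134, 0.0253 without replicate 4, and adjusted p = 0.689 with an estimated correlation). The endothelial list had 1 measured member, Plvap, which rose also when adjusted over the list alone (camera adjusted p = 0.000967, adjusted p = 0.0352 with an estimated correlation, and adjusted p = 0.0913 with that and the line block). A single gene has no correlation between genes to estimate, so the second value is no check on it. The acinar and endocrine list had 1 measured member, the elastase gene Cela1, at 3.57 ± 2.65 CPM with scramble and 2.39 ± 1.84 and 3.65 ± 2.26 CPM with the hairpins (adjusted p = 0.803; list camera adjusted p = 0.96).

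Within the histone deacetylase family, 2 of 9 measured members other than Hdac5 rose, 3 fell and 4 did not pass, with the same counts when adjusted over the list alone. With the line as a block 3 were higher and 4 lower, the added ones being Hdac3 and Hdac11, named after their values were seen, with log2 fold changes of 0.20 ± 0.15 and -0.48 ± 0.24 without the block (adjusted p = 0.323 and 0.139, and 0.000642 and 0.000889 with it). Hdac1 rose by 0.65 ± 0.14 and Hdac6 by 0.35 ± 0.07 (0.21 with shHDAC5-1, adjusted p = 0.0642, or 0.02 with the line block, and 0.50 with shHDAC5-2), while Hdac4, another class IIa deacetylase, went from 44.2 ± 5.90 CPM to 27.4 ± 3.13 and 26.1 ± 2.26 CPM (log2 fold change -0.73 ± 0.09, adjusted p = 3.0e-05). Hdac2 fell by 0.41, with log2 fold changes of -0.80 with shHDAC5-1 and -0.02, not passing, with shHDAC5-2 (adjusted p = 0.902). Hdac10 fell by 0.36, with -0.50 with shHDAC5-1 (adjusted p = 0.00333) and -0.23 with shHDAC5-2 (adjusted p = 0.123, or 0.032 with the line block). The list did not pass (camera adjusted p = 0.517). In the list of SOCS and cytokine receptor signalling, 5 of 22 members rose, 3 fell and 14 did not pass, also when adjusted over the list alone, and the blocked counts were 10 and 3. Socs3, a feedback inhibitor of JAK-STAT signalling on chromosome 11 from 117966079 to 117970047, rose from 16.7 ± 6.98 CPM to 34.1 ± 6.41 and 32.4 ± 4.29 CPM (log2 fold change 1.00 ± 0.21, adjusted p = 0.0019). Socs1 rose by 0.81 ± 0.17 (0.47 with shHDAC5-1, adjusted p = 0.0659, or 0.012 with the line block, and 1.14 with shHDAC5-2), Socs4 fell by 0.64 and Socs7 fell by 0.33 on the log2 scale (adjusted p between 2.1e-05 and 0.00154; list camera adjusted p = 0.506). Stat3 and Yap1 did not pass, with log2 fold changes of 0.13 ± 0.16 and -0.07 ± 0.29 (adjusted p = 0.569 and 0.869). With the line as a block, Stat3 was higher with shHDAC5-1 (0.29, adjusted p = 0.00074) and not with shHDAC5-2 (adjusted p = 0.367). Yap1 was lower in that fit with shHDAC5-2 (-0.20, adjusted p = 0.00435) and not with shHDAC5-1 (adjusted p = 0.544).

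Myc, the growth regulator, fell by 0.36 and Kras fell by 0.20 on the log2 scale (adjusted p = 0.0223 and 0.0311), while Tgfb1 rose by 0.46 ± 0.13 (adjusted p = 0.0113). Myc passed with shHDAC5-1 (-0.42, adjusted p = 0.0296). It did not with shHDAC5-2 (-0.31, adjusted p = 0.0856, or 0.00234 with the line block). Kras passed with shHDAC5-2 (log2 fold change -0.33, adjusted p = 0.00508) and not with shHDAC5-1 (-0.08, adjusted p = 0.507), Tgfb1 with shHDAC5-1 (0.74, adjusted p = 0.00163) and not with shHDAC5-2 (0.18, adjusted p = 0.352), and both differed between the hairpins (adjusted p = 0.0369 and 0.0137). Each of these calls was lost without at least 1 of the lines, at adjusted p between 0.0712 and 0.101 for Myc, between 0.0555 and 0.151 for Kras, and at 0.0516 without replicate 3 for Tgfb1. Trp53 was below the expression filter, at 5.92 ± 0.349 CPM with scramble and 4.6 ± 1.21 and 5.49 ± 0.334 CPM with the hairpins.

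Of the 24 lists 8 passed in camera, and 2 of these with an estimated correlation, the chemokines and the endothelial gene Plvap, while with an estimated correlation and the line block 0 did. Plvap, as the only measured gene of its list, has no correlation between genes to estimate. The remaining lists did not pass as a whole for the mean of both hairpins. Lysosome and autophagy genes passed with shHDAC5-1 alone (camera adjusted p = 0.0184, or 0.0716 with the line block). G1/S genes, lower as a list, passed with shHDAC5-2 alone (camera adjusted p = 0.0462, or 0.0505 with the line block). Neither passed with an estimated correlation (adjusted p = 0.444 and 0.723). In MAPK output genes 10 of 26 rose and 4 fell, with 11 and 5 when adjusted over the list alone and 11 and 7 under the block. The phosphatase gene Dusp4 went from 47.9 ± 10.8 CPM to 28.7 ± 5.47 and 10.7 ± 3.61 CPM, whereas the cytokine gene Lif and the immediate early gene Egr1 rose by 2.29 ± 0.30 and 1.62 ± 0.25 (camera adjusted p = 0.356). In TGF-beta response genes 8 of 23 rose and 3 fell, also when adjusted over the list alone, and 13 and 6 did with the line as a block. The receptor gene Tgfbr2 rose by 1.64 ± 0.12, Junb by 0.97 ± 0.14 and the lysyl oxidase gene Loxl2 by 1.46 ± 0.23 (camera adjusted p = 0.258). In MEF2 and class IIa deacetylase partners and targets 6 of 17 rose and 1 fell, also when adjusted over the list alone, and the blocked counts were 10 and 3. The repressor gene Klf3, the synaptic gene Arc, the insulin receptor substrate gene Irs1 and the activin antagonist gene Fst rose by 0.73 ± 0.10, 1.02 ± 0.20, 0.54 ± 0.11 and 1.08 ± 0.27 (list camera adjusted p = 0.134, 0.0424 without replicate 4, and adjusted p = 0.362 with an estimated correlation).

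Receptor tyrosine kinase and ligand genes included 7 of 24 that rose and 2 that fell, also when adjusted over the list alone, with 11 and 3 under the line block. Egfr and Met rose by 1.11 ± 0.17 and 0.61 ± 0.08, and the EGFR ligand gene Btc fell by 1.62 (camera adjusted p = 0.26). Among p53 targets 5 of 22 rose and 4 fell, also when adjusted over the list alone, with 11 and 5 under the block. The antiproliferative gene Btg2 went from 5.67 ± 0.70 CPM to 35.1 ± 8.30 and 25.3 ± 5.65 CPM and the death gene Bbc3 rose by 1.5 ± 0.14, while Mdm2 fell by 0.47 (-0.92 with shHDAC5-1 and -0.02, not passing, with shHDAC5-2) and Aen fell by 0.66 (camera adjusted p = 0.329). In the unfolded protein and amino acid stress list 12 of 32 rose and 7 fell, with 13 and 7 when adjusted over the list alone and 14 and 11 under the block. The chaperone genes Calr, Dnajb9, Dnajb11 and Hsp90b1 rose by 0.87 ± 0.11, 0.86 ± 0.13, 0.59 ± 0.07 and 0.62 ± 0.10. The list's median log2 fold change was -0.01 and its mean was 0.05 (camera adjusted p = 0.329, direction up).

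In the lysosome and autophagy list 8 of 28 rose and 2 fell, also when adjusted over the list alone, with 13 and 6 under the block. Wipi1, needed for autophagosome formation, rose by 0.86 ± 0.10, and the lysosomal protease genes Ctsz, Ctsa and Ctsd rose by 0.51 ± 0.06, 0.61 ± 0.10 and 0.40 ± 0.08 (camera adjusted p = 0.134). In oxidative phosphorylation 3 of 30 rose and 4 fell, with 2 and 4 when adjusted over the list alone and 7 and 8 under the block. Cytochrome c, Cycs, fell by 1.13, Cox5a fell by 0.87, Uqcrc2 fell by 0.26 and the succinate dehydrogenase gene Sdha rose by 0.37 ± 0.06 (camera adjusted p = 0.506). Cox5a did not pass with shHDAC5-1 (log2 fold change 0.12) and had a log2 fold change of -1.85 with shHDAC5-2. Of 28 G1/S cell cycle genes 0 rose and 3 fell in edgeR's test, the ribonucleotide reductase gene Rrm2, the uracil glycosylase gene Ung and the helicase gene Hells, with log2 fold changes of -1.01, -0.58 and -0.40 (camera adjusted p = 0.358). Rrm2 and Ung did not pass with shHDAC5-1 (-0.01 and -0.12) and had log2 fold changes of -2.01 and -1.05 with shHDAC5-2. The counts were 0 and 2 when adjusted over the list alone and 3 and 10 under the block. Of 30 G2/M genes 4 rose and 1 fell, with 3 and 1 when adjusted over the list alone and 10 and 3 under the block. Ccnb2, Nusap1 and Kif23, which act in mitosis, rose by 0.32 ± 0.08, 0.44 ± 0.12 and 0.36 ± 0.10, and the motor gene Cenpe fell by 0.42 (camera adjusted p = 0.51). With shHDAC5-1 alone 5 were higher and 0 lower, so the fall of Cenpe did not pass with it, and with shHDAC5-2 alone 4 and 4. With the line as a block these counts were 8 and 1, and 4 and 7.

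With shHDAC5-1 alone, Klhl30, Tdpoz4, Ccl9, Upk3bl and Rsad2 had the largest rises, by 4.13 ± 0.52, 3.95 ± 0.87, 3.63 ± 0.37, 3.47 ± 0.47 and 3.37 ± 0.99 on the log2 scale. Apart from Hdac5, the largest falls were those of Car6, Crlf1, Prl2c3, Vcan and Cox6a2, with log2 fold changes of -3.53, -3.47, -2.94, -2.86 and -2.76. Vcan, which encodes the matrix proteoglycan versican, went from 70.6 ± 32.3 CPM with scramble to 9.72 ± 6.50 CPM with shHDAC5-1 (adjusted p = 0.00296). Rsad2 lost its call without replicates 1, 3 or 4 (adjusted p = 0.0762, 0.0675 and 0.0706). In all 3334 genes passed, 1709 higher and 1625 lower, a split that turned to 1631 and 1932 with a correction for GC content and length, 1539 and 1768 with limma, 1521 and 1778 with quantile normalization and 1587 and 1752 with library totals. With the line as a block 6117 genes passed, and without replicate 4 the count was 2076.

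With shHDAC5-2 alone, Tdpoz4, Ccl9, Gbp4, Plekhg4 and Klhl30 had the largest rises, by 4.30 ± 0.88, 4.13 ± 0.38, 3.95 ± 0.66, 3.90 ± 0.47 and 3.87 ± 0.51. Apart from Hdac5, the largest falls were those of Car6, Angptl6, Cox6a2, Stbd1 and Areg, with log2 fold changes of -4.14, -3.44, -3.32, -3.26 and -2.64. Plekhg4 went from 11.6 ± 2.06 CPM with scramble to 173 ± 85.9 CPM (adjusted p = 2.1e-05) and Stbd1 from 58.4 ± 15.4 to 6.10 ± 2.34 CPM (adjusted p = 3.4e-06). In all 4023 genes passed, 2070 higher and 1953 lower. With the line as a block 6570 genes passed. A stricter expression filter gave 2635, and the split turned to 1804 higher and 2567 lower with a correction for GC content and length, 1899 and 2129 with limma, 1798 and 2370 with quantile normalization and 1865 and 2248 with library totals.

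The hairpins were then compared gene by gene to ask how far they shared their effects. Ccl9, Klhl30, Tdpoz4, Car6 and Cox6a2 were among the leading genes with each. In total 1167 genes were higher with each hairpin and 895 lower with each, together 2062, and 91 were called in opposite directions. The split was 1018 higher and 1078 lower with quantile normalization. Independent lists of these lengths would share 334 higher and 299 lower genes. In 20 simulations of unchanged groups every library, the scramble ones too, was drawn from the scramble mean, without differences between lines. At most 1 gene was called with a hairpin, so their shared counts of 0 say nothing about sharing. With the scramble libraries split between the comparisons, in 20 such splits, a median of 698 higher and 464 lower genes were shared. Fewer controls also made the lists shorter. Medians for shHDAC5-1 and shHDAC5-2 were 1165 and 1516.5 higher genes, against 1709 and 2070, and 1110 and 1417 lower, against 1625 and 1953. The log2 fold changes correlated across genes, which are not independent replicates, at r = 0.725, against 0.49 in the simulations and 0.602 with split controls. The 0.49 is the r of noise with shared controls and does not measure the part of 0.725 that comes from them. Their covariance was 0.216, against 0.0262 in the simulations, a difference of 0.19, and it was 0.198 with split controls. With the line as a block, 4006 genes were called with each hairpin in the same direction, and without replicate 4 the count was 1242.

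**Figure D4:**
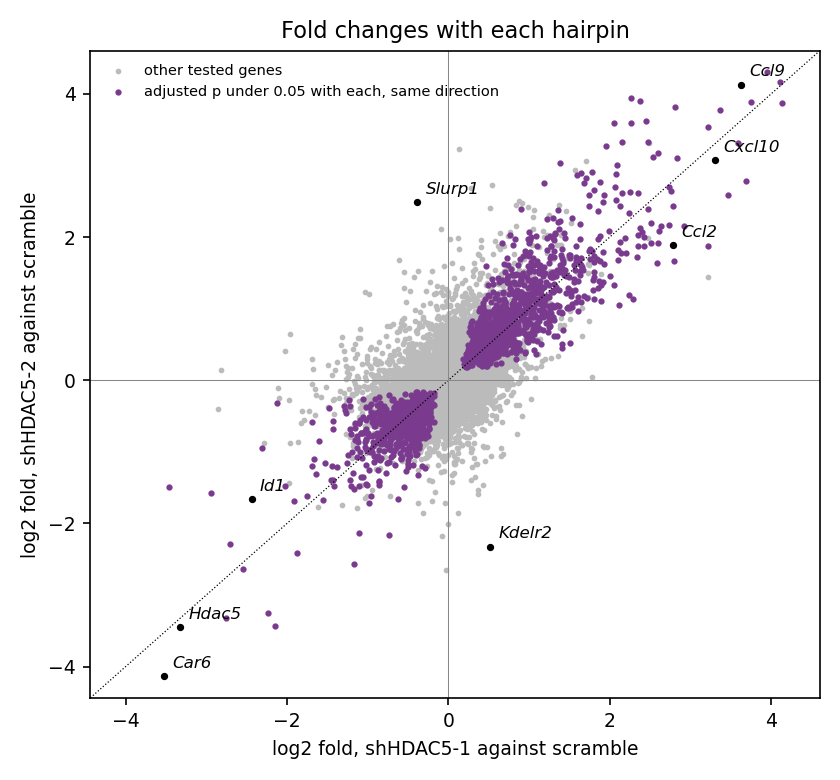
Log2 fold changes over scramble with shHDAC5-1 (horizontal axis) and shHDAC5-2 (vertical axis), each dot a gene tested. The r of 0.725 includes a part that comes from the shared scramble libraries. Simulations of unchanged groups with simulated shared controls gave 0.49, which does not measure that part.

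Levels also differed directly between the hairpins. Kdelr2, which encodes a receptor that returns proteins to the endoplasmic reticulum, stood at 191 ± 27.1 CPM with scramble, 273 ± 44.8 with shHDAC5-1 and 38.2 ± 7.27 with shHDAC5-2, a difference between the hairpins of 2.84 ± 0.16 on the log2 scale (adjusted p = 3.4e-08). Rrm2 and Cox5a were also higher with shHDAC5-1 than with shHDAC5-2, by 2.00 ± 0.24 and 1.97 ± 0.15, as were Dpagt1, the first enzyme of N-glycan synthesis, and the adhesion receptor gene Gpr124, by 1.96 ± 0.11 and 2.09 ± 0.39. Lower with shHDAC5-1 were the potassium channel gene Kcnh2, with a difference of -2.20 ± 0.25 (adjusted p = 2.5e-05), and Vcan, the neurite gene Nrn1, the homeodomain gene Hopx and the secreted peptide gene Slurp1, with differences of -2.46 ± 0.61, -2.43 ± 0.60, -2.40 ± 0.66 and -2.88 ± 0.64. The Vcan call was lost without replicate 1 (adjusted p = 0.0541) and that of Hopx without replicates 1, 2 or 3 (adjusted p = 0.0678, 0.064 and 0.0527).

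Interferon response genes were less high with shHDAC5-1 than with shHDAC5-2. Of 28 members 14 were lower and 0 higher, 18 were lower when adjusted over the list alone and 24 under the line block, among them Parp14, with a difference of -1.13 ± 0.19, and Ddx58, with -0.47 ± 0.16. The camera adjusted p was 6.1e-06, and the adjusted p = 0.869 with an estimated correlation. Mesenchymal markers were also lower with shHDAC5-1, with 6 of 27 past the threshold, also when adjusted over the list alone, Sparc and Col1a1 among them, and 17 under the line block (camera adjusted p = 0.0347, and adjusted p = 0.869 with an estimated correlation). G1/S genes were higher, with 8 of 28 past the threshold, 9 when adjusted over the list alone and 15 under the block (camera adjusted p = 0.00317, and adjusted p = 0.869 with an estimated correlation). Over all genes 2317 differed between the hairpins, 1133 higher and 1184 lower with shHDAC5-1, a split that turned to 1346 and 1030 with a correction for GC content and length, 1266 and 1066 with quantile normalization and 1215 and 1068 with library totals. With the line as a block 5183 genes differed, and without replicates 1 or 4 the counts were 1402 and 1376.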

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

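The searches for short sequences in 3′ untranslated regions and the tests of leukocyte transcripts, of GC and length offsets, of the number of control constructs and of the splits of libraries in this part were chosen after the results had been seen; the tests of the share of differing genes with a match and of the larger fold were fixed before.

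The hairpins differed at 2317 genes, while the difference in Hdac5 itself did not pass. On the log2 scale, shHDAC5-1 minus shHDAC5-2 was 2.84 for Kdelr2, 2.09 for Gpr124, 2.00 for Rrm2, 1.97 for Cox5a and 1.96 for Dpagt1. It was -2.88 for Slurp1, -2.46 for Vcan, -2.43 for Nrn1, -2.40 for Hopx and -2.20 for Kcnh2. Genes called with both hairpins differed in size between them as well, with 1.38 for Esd, 1.29 for Angptl6, 1.03 for Stbd1, 0.90 for Ccl2, -1.0 for Plvap, -1.54 for Plekhg4, -1.97 for Crlf1 and -1.37 for Prl2c3. It was 0.56 for Tgfb1 and 0.25 for Kras, of the fixed single genes, and -0.78 for Hdac2 and -0.28 for Hdac6, of the deacetylase list. The Ccl2 difference had an adjusted p of 0.0496. Of the lists, interferon response (adjusted p = 6.1e-06), mesenchymal markers (adjusted p = 0.0347) and G1/S genes (adjusted p = 0.00317) differed in camera, and none did with an estimated correlation. Of 100 splits of the libraries, only the real split gave as many differing genes, and the highest other gave 87. These splits ignore the pairing by line. Only 16 splits within lines exist, where the highest other gave 0 genes with the line block. That is too few for a share under 0.05, so chance cannot be formally excluded.

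A difference in knockdown strength as the cause of the 2317 differing genes was argued against, since the fold was larger with shHDAC5-2 in 59.0% of them and with shHDAC5-1 in 40.96%, whereas unequal knockdown, whichever hairpin left less Hdac5, required over 80% with that hairpin. A candidate explanation is that each hairpin acted on other transcripts through short matches to its own seed sequence: among 16020 heptamers in the 3′ untranslated regions of 9702 genes, with the line as a block, carriers of GAATGGC ranked lowest with shHDAC5-1 relative to shHDAC5-2 (score -12.1, beyond the -4.78 of 100 shuffles) and carriers of GCTGCCA lowest with shHDAC5-2 (score 7.76, beyond 4.92). Of the genes lower with shHDAC5-1, 71.1% held a heptamer beyond the shuffles, against 50.5% of genes that did not differ (odds ratio 2.41, Fisher's exact test p = 1.0e-39), and for shHDAC5-2 the shares were 58.5 and 38.9% (odds ratio 2.21, Fisher's exact test p = 5.1e-34), with the heptamers picked on the same data. These Fisher tests restate the ranking and are no separate evidence for the explanation. The shifts were small: the median difference between the hairpins was -0.168 among carriers of GAATGGC, against -0.00074 among the other genes searched. For GCTGCCA it was 0.0445, against -0.02. Single genes differed by far more, such as Kdelr2 by 2.84. Whether every differing gene has such a match stays open, since 64.9% of the 2237 searched held one and 785, Cox5a and Kcnh2 among them, did not, coding sequences were not searched, and Hopx and Slurp1 hold one for shHDAC5-1 but were not called lower with it than with scramble (log2 fold changes 0.28 and -0.39), having risen with shHDAC5-2 (2.68 and 2.49). GAATGGC and GCTGCCA occur in the Hdac5 transcript, as do 21.8% of all heptamers. Of the 5 leading heptamers per hairpin, ATGGCTA for shHDAC5-1 and TTCGCTG and GTTCGCT for shHDAC5-2 do not. The hairpin sequences are not given in the sources used here, and a biological difference between the hairpins was not tested.

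For the mean of both hairpins, the chemokine, NF-kB, interferon and cholesterol lists were higher in camera. With an estimated correlation only the chemokines passed (adjusted p = 0.0352, 0.0969, 0.0592 and 0.0592), or none with the line block as well. Tested per hairpin with an estimated correlation, interferon response passed with shHDAC5-2 (camera adjusted p = 0.0327) and not with shHDAC5-1 (0.209). Leukocytes in the hairpin libraries were argued against, since 5 abundant leukocyte transcripts reached at most 0.519 CPM in any library while Ccl2 rose by 63.9 CPM. A trend with GC content or length was argued against as the whole cause, since with offsets for both and the line block the highest camera adjusted p of the 4 lists was 2.4e-09. Effects of the scramble construct itself cannot be told apart from effects of knockdown, because there was 1 control construct and no group without a hairpin. That loss of HDAC5 may raise these genes stays a hypothesis beside it.

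Of 61 sets of 5 lines examined for a line standing apart, 2 had one, where chance gives about 1 in 20. The log2 fold of Angptl6 over its own line's scramble, with 0.5 CPM added to each level, was -1.58 in replicate 3, against -3.02 to -2.77 in the other lines. The median of the acinar and endocrine list, which is Cela1 alone, was 1.75 in replicate 5, against -0.46 to -0.07 in the others.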

How the results depend on the processing

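The values with limma on log2(RPKM + 1), with library totals and with GC and length offsets were chosen after the data had been seen. Hdac5 stayed between -3.50 and -3.29 on the log2 scale without each line in turn. Of the values of named genes recomputed under scalings, another test, the block and each line left out, 574 kept direction and side of the threshold, 15 lost the call, all with a line left out, and 1 reversed.

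With the replicate block the counts were 6592 for both hairpins, 6117 for shHDAC5-1, 6570 for shHDAC5-2, 5183 between the hairpins and 4006 shared. The block changed no call in 59 values of genes named by rule or in the fixed set, the latter for the mean of both hairpins. Of the lists for that mean, it moved only YAP and TEAD targets and mesenchymal markers across the threshold. Calls of other list members, also with single hairpins, can change with the block, as the blocked counts in the results show. Other settings combined with the block stayed within 1.5 times of the blocked counts. DESeq2, other scalings, limma, no filter, robust empirical Bayes and fits of only the groups compared stayed within 1.5 times of the counts without it. A filter at RPKM 5 tested fewer genes (6603) and gave 2702 for both hairpins and 2635 for shHDAC5-2. GC and length offsets turned the split for shHDAC5-2 to 1804 higher and 2567 lower, against 2070 and 1953. They moved the split by under 10 percentage points for both hairpins (1833 higher and 2600 lower, against 2025 and 2073) and turned it for shHDAC5-1 (1631 and 1932, against 1709 and 1625) and between the hairpins (1346 and 1030, against 1133 and 1184). Limma, quantile normalization and library totals also gave more lower than higher genes with each hairpin, and the shared genes went from 1167 higher and 895 lower to 1018 and 1078 with quantile normalization and to 1051 and 1012 with limma. No filter gave 2532 higher and 2038 lower for both hairpins, 2113 and 1348 for shHDAC5-1, 2457 and 1848 for shHDAC5-2 and 1055 and 802 between the hairpins. Across scalings the median gene moved by at most 0.06 on the log2 scale.

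Leaving out each line in turn, which leaves fewer libraries, gave 2927 to 4121 genes for both hairpins, 2933 to 3975 for shHDAC5-2, 2076 to 3394 for shHDAC5-1 (lowest without replicate 4), 1376 to 2091 between the hairpins (1376 without replicate 4 and 1402 without replicate 1) and 1242 to 2116 shared (lowest without replicate 4). Why replicate 4 weighed more was not tested. Ccl7, not called, ranged from -0.35 to 4.8e-05, reversing without replicate 3 (adjusted p = 1.0). Uncalled lists reversed direction for G1/S (adjusted p 0.113 to 0.965, without replicate 3), G2/M (0.0969 to 0.731, without replicate 2 at 0.706) and unfolded protein (0.149 to 0.896, without replicate 3).

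The number of called lists was 2 of 24 with an estimated correlation (the single gene Plvap among them), 8 with the block, 0 with both, 12 with fry and 7 to 11 without each line. YAP and TEAD targets also lost the call with limma on log2(RPKM + 0.1) (adjusted p = 0.0652), and mesenchymal markers gained it with quantile normalization (0.0273), library totals (0.045) and GC and length offsets (0.032). The acinar list, Cela1 alone, reversed with quantile normalization (adjusted p = 0.98), library totals (0.993), GC and length offsets (0.957, and 0.934 with the block) and limma (0.97); the cause was not tested. At 94.6 M counts or more per library, Il6 stayed below the expression filter and was not tested. In simulated data 91.0% of 2-fold changes with both hairpins were recovered, and 50.7% of 1.5-fold changes, or 32.8 and 40.3% of the latter with shHDAC5-1 and shHDAC5-2 alone.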

Other observations

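All tests of splits in this part were chosen after the results had been seen, except those of the shared genes and of the number of lists; the genes of the next paragraphs were also chosen after their values were seen.

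The unfolded protein and amino acid stress list did not pass as a whole (camera adjusted p = 0.329). Its 12 rises included Sdf2l1, Creld2, Pdia6 and Hspa5, by 0.92 ± 0.20, 0.82 ± 0.16, 0.67 ± 0.12 and 0.44 ± 0.10 on the log2 scale. Its 7 falls were those of Trib3, Slc7a11, Ppp1r15a, Mthfd2, Asns, Atf4 and Shmt2. These are calls of the mean of both hairpins. With shHDAC5-1 alone 11 members were higher and 1 lower, and with shHDAC5-2 alone 13 and 10. Trib3, a pseudokinase induced by ATF4, went from 133 ± 22.7 CPM with scramble to 80.9 ± 27.9 and 43.4 ± 21 CPM (log2 fold change -1.17 ± 0.23, adjusted p = 0.0011). The cystine transporter gene Slc7a11 fell by 0.95 (adjusted p = 0.013) and Atf4 itself fell by 0.47 (adjusted p = 0.0196).

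Among TGF-beta response genes, all 3 falls were those of inhibitors of DNA binding that respond to BMP signals. Id1, Id2 and Id3 had log2 fold changes of -2.05, -0.61 and -1.80, Id2 without passing with shHDAC5-2 (-0.31), while the protease inhibitor gene Serpine1 rose from 87.2 ± 31.6 CPM to 260.3 ± 86.2 and 276 ± 121 CPM (log2 fold change 1.62 ± 0.31, adjusted p = 0.000937). Of the EGFR ligand genes, Areg fell by 2.59 and Btc fell by 1.62, whereas Hbegf rose by 1.02 ± 0.22 (adjusted p = 0.00202) and Ereg did not pass (log2 fold change -0.07 ± 0.26, adjusted p = 0.848). The interferon-induced antigen processing genes Psmb8, Psmb9 and Tap1 rose by 2.27 ± 0.30, 2.55 ± 0.27 and 1.06 ± 0.25.

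Other splits of the 15 libraries into groups of the same sizes, 100 with the real one, were fitted in the same way. For both hairpins against scramble only the real split reached 4098 genes, and the highest other gave 184. The same held for shHDAC5-1 (3334, highest other 565), for shHDAC5-2 (4023, highest other 0) and for genes shared by both hairpins (2062, highest other 0). These splits ignore the pairing of libraries by line, so on their own they do not exclude chance. Among splits that parted all 5 lines as the real one does, between 10 and 14 per comparison, the highest gave 0 genes. With the line as a block, splits within lines gave at most 3419 genes for both hairpins, against 6592 in the real split, which alone of 100 reached that count, and chance can be excluded. Shared genes numbered 4006 in the real split and at most 2021 in another, so chance can be excluded for them too. Only 16 splits within lines exist for each hairpin and between the hairpins, too few for a share under 0.05 (real 6117, 6570 and 5183, highest other 1, 0 and 0).

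For the number of called lists chance cannot be excluded, since 32 of 100 splits gave 8 or more and the highest other gave 14, or 11 among splits parting all 5 lines. The lists themselves differed. A camera p as small was reached by 1 of 100 splits for chemokines, 2 for NF-kB targets, 3 for interferon response, 2 for cholesterol biosynthesis and 1 for the endothelial gene Plvap, the real split included. In 100 splits within lines, with the block, these counts were 3, 1, 3, 3 and 2. For the camera p of each of these taken singly the share was thus under 0.05, with no allowance for the 24 lists. The lists were examined because they were called among the 24, so these shares do not exclude chance for them. With an estimated correlation only the chemokines and Plvap passed (adjusted p = 0.0352 for both, against 0.0969 for NF-kB targets and 0.0592 for interferon response and for cholesterol biosynthesis). Plvap, a single gene, has no correlation to estimate. Even singly, chance cannot be excluded for the camera p of YAP and TEAD targets (12 splits), epithelial markers (38) and glycolysis and hypoxia (19). The smallest p of another split was 3.1e-08 for chemokines, against 1.2e-09, 1.5e-08 for NF-kB targets, against 1.4e-07, 4.6e-15 for interferon response, against 3.7e-14, and 1.6e-17 for cholesterol biosynthesis, against 1.1e-14. For Plvap it was 0.036 against 0.000201, for YAP and TEAD targets 0.000232 against 0.0129, for epithelial markers 3.3e-08 against 0.0159 and for glycolysis and hypoxia 4.1e-07 against 0.00148. The median of the members' log2 fold changes is not set against other genes. Taken singly, it was as large in under 5 of 100 splits for YAP and TEAD targets and for glycolysis and hypoxia. For YAP and TEAD targets it was 0.273 (highest other 0.203, 1 of 100 splits), and 0.261 with the line block (highest other 0.235, 1 of 100). For glycolysis and hypoxia it was 0.357 (highest other 0.319, 1 of 100), and 0.34 with the block (highest other 0.324, 1 of 100). For epithelial markers a median as large came in 2 of 100 splits that ignore the pairing (0.674, highest other 0.689). Within lines, with the block, it came in 7 of 100 (0.634, highest other 0.913), so chance cannot be excluded. The median was examined for these called lists only because their camera p was matched by 5 of 100 splits or more. The medians of the uncalled SOCS and MEF2 lists were as rarely reached (4 and 2 of 100 splits, and 1 and 1 with the block). The median therefore does not set the YAP and glycolysis lists apart from uncalled lists.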
